A study of Homo sapiens with 4 samples.

How the data were processed

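Poly(A) site sequencing reads the junction between the body of an mRNA and its poly(A) tail, so that a read reports where a transcript was cleaved and polyadenylated. It was applied to 4 libraries of DICER(ex5) cells, a hypomorphic DICER line made from HCT116, a human colon cancer cell line. Dicer is the ribonuclease that cuts microRNA precursors. Per the labels' protocols, poly(A)+ RNA was fragmented with alkali, fragments of 50 to 100 nt were cut from a gel, and cDNA was made with an anchored oligo(dT) primer that carried 6 degenerate bases and a sample barcode. Whether the degenerate bases were used to remove PCR duplicates is not given in the sources used here. Oligo(dT) can also prime on A-rich stretches inside a transcript, and no genome sequence was used here to mark such regions. The design text calls the libraries biological quadruplicates, and no label gives a day or a batch.

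The authors deposited a table of raw counts of reads per poly(A) region and library, with the chromosome, start, end and strand of each region, per the file headers. The submitters' processing notes name Bowtie2 2.2.5 and the build hg19. How reads were joined into regions, and with which filter, is not given in the sources used here. In the table itself, every region had at least 11 reads in its highest library. No regions of a strand overlapped, and the nearest neighbours lay 11 bases apart. Some regions have equal start and end, so widths were taken as end minus start plus one. Whether positions count from one or from zero is not stated, and they are printed as deposited. The regions are common to all libraries, so a count can be compared between libraries, while a region missing from the table cannot be scored.

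The table pairs no region with a gene name, and no annotation of hg19 was used here. Regions are therefore named by position, and the planned lists of genes, the genomic category of regions, the search for poly(A) signals and A-rich flanks and the values of DICER1 are not reported here. In place of genes, regions of a strand that lay within 5 kb of the next were joined into a locus. The distance was chosen after seeing the data, and 1, 2 and 10 kb were tried as well. A locus can join neighbouring genes or split a gene with distant sites. The strand was read as that of the transcript. Of opposite-strand pairs of regions within 2 kb that did not overlap, 1611 had the plus-strand region on the left, as 3' ends of converging transcripts would, and 620 had it on the right.

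The following choices were made before the data were examined, for genes, and were then applied to loci. A region passed with at least 10 reads summed over the libraries and 5% of the reads of its locus. The distal region share is the share of a locus's reads in passing regions that fell in the most 3' one. The plan took the most 3' region of an annotated 3' UTR or terminal exon, which could not be applied without an annotation. The distal share was computed as follows. It was computed per library for loci with several passing regions and at least 100 reads, and its mean and SD over the 4 libraries are given. The position of the strongest region was compared with 10000 draws that placed it at random among the regions of each locus (two-sided; ties shared). Agreement was measured on log2 of CPM (counts scaled to the library total) plus 1. Named loci were the 10 with the most reads and, among loci with several regions and at least 100 reads in every library, 5 each with the highest share, the lowest share (both within 5% to 95%), the share closest to 50%, the longest span and the most regions. For the loci with the most regions, the minimum of 100 reads in every library was not planned. Without it, the most passing regions in a locus was 9. The planned rule on members of gene lists could not be applied.

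Usage of the distal region was compared between libraries by Fisher's exact test per locus, two-sided, on counts thinned at random to the smallest library total, with Benjamini-Hochberg adjustment within each pair of libraries and a threshold of 0.05. Such a test compares libraries, not conditions. This comparison was chosen after seeing the data. Fisher's test treats reads as independent molecules, so duplicates or other spread beyond sampling can add to its calls. On simulated data with the odds of the distal region tripled in 200 of 5070 loci, the unthinned test of library 1 against library 3 recovered 60.5% of them and called 5 unchanged loci, and with no change library 1 against library 4 gave 0 calls. The simulated libraries varied by sampling alone, and thinned counts were not simulated. These figures therefore do not give the error rate of the thinned test on libraries that vary more. Intervals are 95% Wilson intervals. They and the limits from a count of 0 (3 counts) cover counting error only, since reads without duplicate removal are not independent molecules, and loci of a library are not independent replicates.

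The libraries held 5211279, 2163977, 5713530 and 3984278 reads in regions, so that a count of 0 allows up to 0.576, 1.39, 0.525 and 0.753 CPM. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used. There was 1 group and no control, so no groups were compared. Alternatives covered the minimum reads and share of a region, merging of ends within 100 bases, loci with at least 500 reads, each library left out, the pseudocount, the joining distance, regions of 10 bases or fewer left out, and each pair of similar libraries on its own.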

Results

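The data collected were read counts at 31081 poly(A) regions of DICER(ex5) cells, in 4 libraries of a single group. The table held 17073064 reads. Library 1 had 5211279 reads, library 2 had 2163977, library 3 had 5713530 and library 4 had 3984278. With no parental line or other control in the series, the comparisons are between poly(A) regions of a locus and between libraries. Positions are on hg19.

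Poly(A) regions were found on all autosomes and both sex chromosomes, on both strands, with 15786 on the plus and 15295 on the minus strand. Chromosome Y had 15 regions with 0.00649% of the reads, and only 2 of them were wider than 10 bases. The median region was 27 bases wide and held 98 reads summed over the libraries. Reads were concentrated in few regions: the 3453 regions with 1000 reads or more held 72.2% of all reads. Chromosome 1 had the most regions, 3096, with 9.63% of the reads. Chromosomes 19 and 17 held 9.33% and 8.57% of the reads in 1467 and 1742 regions, while chromosome 13 held 1.31% in 671 and chromosome X 2.42% in 883. Reads were present in all 4 libraries at 28372 regions (91.3%), and in a single library at 16.

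The strongest poly(A) region lay on the plus strand of chromosome 12, from 6647495 to 6647556, and its locus gave 8202 ± 948 CPM (SD, n = 4), which are reads scaled to the library total. The next loci were on the minus strand of chromosome 12 (49521556 to 49521604, 5569 ± 340 CPM), the minus strand of chromosome 8 (146015128 to 146015216, 5172 ± 276) and the plus strand of chromosome 2 (85133777 to 85133830, 4596 ± 1021). The loci at 19376216 on chromosome 9 and 72205975 on chromosome 17 gave 4337 ± 445 and 3841 ± 451 CPM. Those at 79800405 on chromosome 10, 50050249 on chromosome 14, 93307429 on chromosome 1 and 58906135 on chromosome 19 gave 3379 ± 285, 3175 ± 748, 3080 ± 348 and 2772 ± 400. Together these 10 loci held 4.37% of all reads. Each of the 10 had exactly 1 region that passed the 5% minimum, although the locus on chromosome 9 contained 7 regions in all.

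How many poly(A) sites a transcript end uses was asked next. Joined within 5 kb, the regions made 17963 loci, of which 5358 (29.8%, interval 29.2% to 30.5%) had 2 or more passing regions. Exactly 2 regions were found at 3253 loci, 3 at 1299, 4 at 522, 5 at 186 and 6 or more at 98. Among loci with 100 to under 1000 reads, 45.4% (44.3% to 46.6%) had several regions, and among those with 1000 to under 10000 reads, 47.1% (45.4% to 48.8%). The 213 loci with 10000 reads or more had several regions in 31.0% (25.2% to 37.5%), below both. The first 2 classes held 7422 and 3465 loci. The other loci had under 100 reads and are counted in the 29.8%, which they pull below all of these classes. Of the 5358 loci with several regions, 5070 had at least 100 reads. Each library was also counted alone at the same depth, with a minimum of 3 reads per region. The share of loci with several regions was then 32.0% ± 2.15 (SD, n = 4). It was 29.9% and 30.3% in libraries 1 and 2 and 33.9% and 33.7% in libraries 3 and 4. The 29.8% used a minimum on reads summed over libraries, so these values are not directly comparable with it. With each pair's reads pooled, the higher share in libraries 3 and 4 did not come with more such loci. Several regions were found at 5314 of 17617 loci in libraries 1 and 2, and at 5078 of 14908 in libraries 3 and 4. The share over all libraries depends on the loci admitted: it was 19.5% when regions were joined within 1 kb, and 49.9% among loci with at least 500 reads.

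The loci with the most regions among those deeply read had 7 or 8 passing regions each. On the plus strand of chromosome 8 (6615001 to 6619029), 8 passing regions shared 1239 reads, and the most 5' one took 22.4% of them (SD 2.87, n = 4). On the minus strand of chromosome 5 (114948902 to 114951436) and of chromosome 16 (89348549 to 89350873), 8 regions each had their first and last ends 2481 and 2279 bases apart, and the distal ones took 9.27% ± 3.87 and 9.05% ± 2.24 (SD, n = 4). With a 10% minimum fewer regions counted, and the distal shares of these loci were 31.9% and 50.7%. On the plus strand of chromosome 2 (122523206 to 122525433), 1 of 7 regions took 47.4% ± 6.61, and on that of chromosome 13 (80127038 to 80130219), 1 of 7 took 36.3% ± 1.73 (SD, n = 4).

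Proximal and distal usage was compared at the 5070 loci with several regions and at least 100 reads. The distal region took a median of 43.0% of the reads of a locus (SD 0.434, n = 4), and it took over 50% of them at 44.4% of loci (SD 0.355, n = 4). The median was 42.5% and 42.9% in libraries 1 and 2 and 43.3% and 43.5% in libraries 3 and 4, but the order turned when each pair's loci were drawn from its own reads: 43.2% ± 0.152 in libraries 1 and 2 and 41.2% ± 0.182 in libraries 3 and 4 (SD, n = 2). Loci lay more often near either end of the range than in the middle: the distal share, pooled over libraries, was under 20% at 1414 loci, from 40% to under 60% at 766 and 80% or more at 1012. These counts take loci with any number of regions together, and more regions alone lower the distal share. The shape was not examined at loci with 2 regions alone. The distal region was above 50% in all 4 libraries at 1874 loci and below 50% in all 4 at 2422. The remaining 774 loci lay on both sides of 50%, or had exactly 50% or no reads in a library. The SD of a locus's distal share between libraries had a median of 4.54 percentage points. It was 10 points or more at 854 loci. Counting noise adds to this spread and to the 774 remaining loci, most where a locus has few reads. How much it adds was not estimated.

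**Figure D1:**
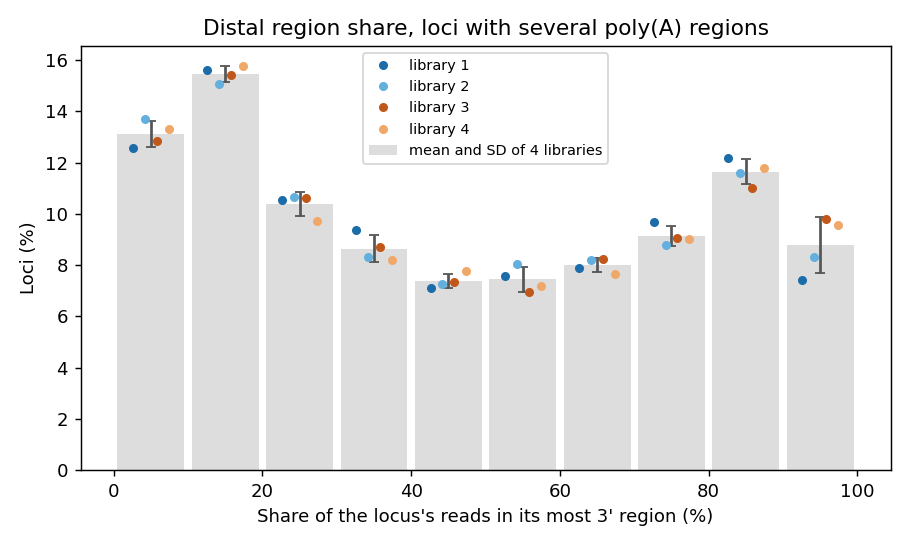
Distribution of the distal region share over the 5070 loci with several poly(A) regions and at least 100 reads; the x axis is the share of a locus's reads in its most 3' region (%) and the y axis the share of loci (%). Bars and error bars are the mean and SD of the 4 libraries and points are libraries; the lowest bars, at 7.38% and 7.45% of loci, are the classes on both sides of 50%.

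The distal share was lower where more regions divided the reads. It had a median of 60.1% ± 0.710 at the 2971 loci with 2 regions, 33.7% ± 0.646 at the 1293 with 3 and 18.7% ± 0.129 at the 806 with 4 or more (SD, n = 4). Sharing alone lowers it, so the position of the strongest region was compared with random placement among the regions of the same locus. The strongest region was the most 3' one at 49.3% of loci, against 41.4% at random (95% of draws from 40.1% to 42.7%; two-sided permutation p = 0.0002, the smallest the draws can give). It was the most 5' one at 34.2% (p = 0.0002 by the same permutation, on the low side). By library, the strongest region was the most 3' one at 48.8% ± 0.169 of loci (SD, n = 4). With 2 regions the share was 57.6% (55.8% to 59.3%), with 3 it was 43.2% (40.6% to 45.9%) and with 4 or more 28.7% (25.6% to 31.9%), against 50%, 33.3% and 22.7% at random. Loci are not independent replicates, and a locus may join neighbouring genes.

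Neighbouring 3' ends within loci lay a median of 638.5 bases apart. At loci with 2 regions the median distance was 800 bases, and 55.2% had ends within 1000 bases. The median distal share varied with this distance. Where the ends lay over 100 and up to 1000 bases apart (1284 loci), the median distal share was 64.3% ± 0.588, against 52.1% ± 1.25 at up to 100 bases (355 loci) and 57.2% ± 0.705 beyond 1000 bases (1332 loci; SD, n = 4). The first difference was 12.1 ± 0.743 percentage points and the other 7.10 ± 0.303 (SD, n = 4). The libraries read the same loci, so these SDs leave out the spread over loci. With loci redrawn within each class, the 95% bootstrap intervals were 4.34 to 19.3 and 1.85 to 11.5 points. These distance classes and tests were chosen after seeing the data, and the intervals do not allow for that choice. The distances are also limited by the joining distance of loci, which was likewise chosen after seeing the data. Ends far apart may belong to neighbouring genes, which cannot be told without an annotation. The differences between classes were not recomputed with other joining distances. Whether the spacing of sites within a single transcript relates to distal usage was therefore not tested. Over the 6 classes of the figure, Kruskal-Wallis H of the distal share was 17.6 across the 2971 loci (permutation test over loci, p = 0.0037). Across loci, no monotonic relation of distance and distal share was detected (Spearman rho = -0.03, permutation p = 0.17; Pearson r of log10 distance = -0.02).

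Single loci show the range of usage. Among loci with at least 100 reads in every library, the 5 highest and the 5 lowest distal shares within 5% to 95% were taken. The highest were on the minus strand of chromosome 3 (172348421 to 172348737, 95.0% ± 1.05, ends 239 bases apart) and of chromosome 11 (64532048 to 64533265, 94.9% ± 0.790, ends 1183 bases apart; SD, n = 4). The loci on the plus strand of chromosome 18 at 72188153 and 20606326 had 94.8% ± 3.83 and 94.8% ± 1.21, and that on the minus strand of chromosome 13 at 23902957 had 94.8% ± 2.90 (SD, n = 4). At the other end, the distal region took 5.01% ± 0.833 on the minus strand of chromosome 22 (50883421 to 50885270) and 5.07% ± 0.300 on that of chromosome 7 (44605008 to 44605434; SD, n = 4). On the plus strand of chromosome 12 (66358525 to 66360089) it took 5.04% ± 0.876, but its neighbour ended within 100 bases and held 89.9% ± 3.73 (SD, n = 4). When ends within 100 bases were merged, the distal share of that locus was 95.0%. These loci lie near the 5% minimum or its counterpart at 95%, and leaving out a library changed each of them. Without library 1, the loci on chromosomes 3, 7, 13 and 18 (both) no longer had 2 passing regions. The same held without library 2 for those on chromosomes 7, 13 and 18 (72188153), without library 3 for those on chromosomes 11, 12 and 22, and without library 4 for those on chromosomes 7, 18 (20606326) and 22. On chromosome X (106893303 to 106897188) and chromosome 14 (57667219 to 57673540) the distal shares were 5.01% ± 1.26 and 5.04% ± 2.31 (SD, n = 4). Without library 3 the distal region of each dropped out, and the share of the next one became 88.2% and 25.8%. Without library 4 the share on chromosome X became 89.0%.

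The 5 loci closest to an even division were taken as well. The best read of them was on the plus strand of chromosome 2 (217070101 to 217071028), where the 2 regions, with ends 860 bases apart, shared 16865 reads and the distal one took 49.9% ± 4.23 (SD, n = 4). The distal region took 50.3% ± 1.88 on the minus strand of chromosome 4 (39500366 to 39501048), 50.3% ± 3.36 on that of chromosome 15 (44162954 to 44165744), 50.3% ± 3.52 on that of chromosome X (20168016 to 20172957) and 49.8% ± 6.36 on that of chromosome 19 (39327005 to 39332224; SD, n = 4). Joined within 1 or 2 kb, the chromosome X locus had a distal share of 30.4%, since its distal region then stood alone.

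The longest loci spanned 11206 to 16801 bases between the first and the last 3' end. On the minus strand of chromosome 5 (34897160 to 34913994), a region at 34908642 took 48.4% ± 6.58 of the reads and the distal one 9.18% ± 3.0 (SD, n = 4). The distal share of this locus was 27.6% with a 10% minimum, and 53.3% and 21.9% for the part left with several regions when joined within 1 and 2 kb. On the minus strand of chromosome 10 (129894917 to 129907314), the distal of 6 regions was the strongest with 36.5% ± 7.80 (SD, n = 4). On the plus strand of chromosome 6 (7575019 to 7586952), a region at 7586788 took 72.1% ± 14.2 (SD, n = 4), with 61.6% and 58.1% in libraries 1 and 2 and 84.6% and 84.1% in libraries 3 and 4. The most 5' region of that locus took 20.2% and 23.6% in libraries 1 and 2 and 3.96% and 2.58% in libraries 3 and 4. On the plus strand of chromosome 14 (24774385 to 24786156) a region at 24777358 took 68.0% ± 4.71, and on that of chromosome 10 (75531905 to 75543150) the distal one took 66.0% ± 2.57 (SD, n = 4). With no share minimum, a weak region further downstream became the distal one of the latter, with 4.19%; joined within 1 kb, the value was 6.50%. Long loci may hold the ends of neighbouring genes.

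**Figure D2:**
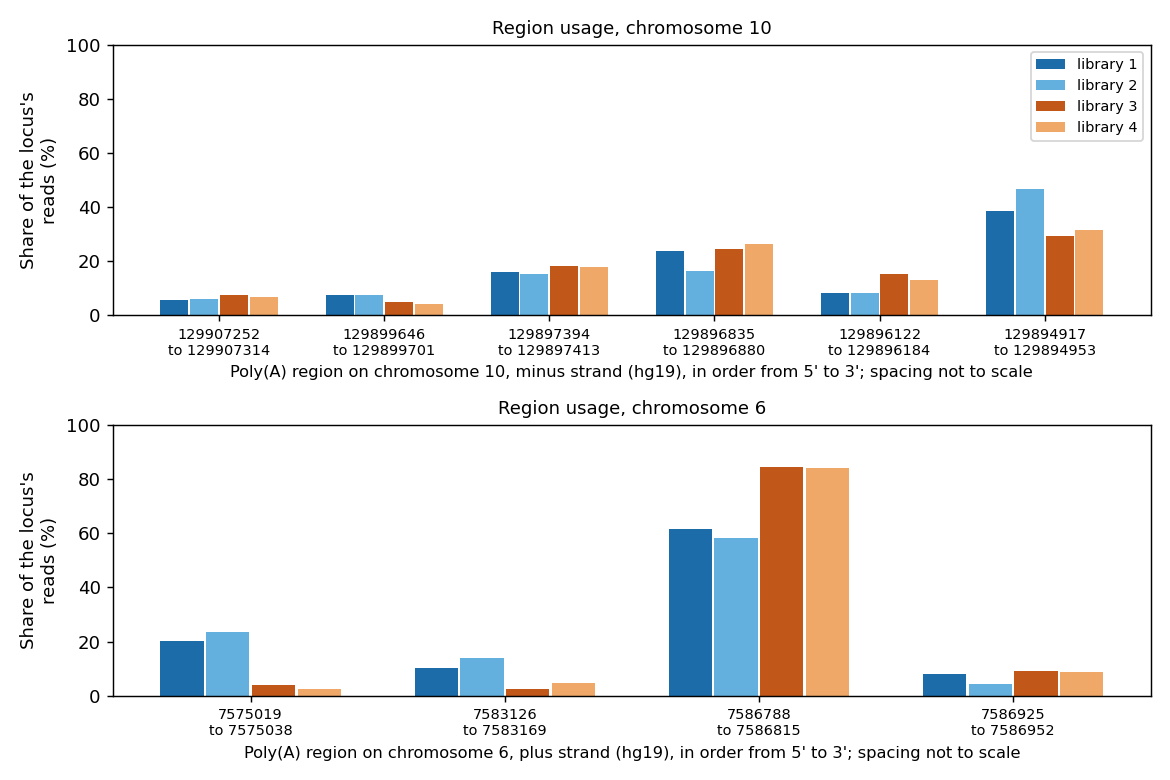
Share of the reads of a locus in each passing region (%, y axis) at the locus on the minus strand of chromosome 10 (top) and at that on the plus strand of chromosome 6 (bottom); the x axis lists the regions by hg19 position from 5' to 3'. Bars are libraries; on chromosome 6 the region at 7586788 holds 61.6% and 58.1% in libraries 1 and 2 and 84.6% and 84.1% in libraries 3 and 4.

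Levels of the poly(A) regions differed between libraries by unequal amounts. Across regions, Pearson's r of log2 CPM was 0.97 between libraries 1 and 2 and 0.98 between libraries 3 and 4, but 0.84 to 0.87 in the other pairs of libraries. Spearman's rho was 0.94 and 0.97 against 0.76 to 0.79. Regions are not independent replicates, and these values describe the 4 libraries. At the same depth, libraries 3 and 4 had a chi-square of 1.23 per region and libraries 1 and 2 one of 1.56, against 1 from sampling alone. No pair agreed within sampling noise and n is given as 4 libraries. Repeat preparations of a culture, with PCR duplicates kept, could also exceed 1, so the SD and n may partly measure technical spread. The other pairs had 6.32 to 8.85. Of the 3453 regions with 1000 reads or more, 0.145% differed over 2-fold between libraries 1 and 2, 0% between libraries 3 and 4 and 4.72% to 8.51% in the other pairs.

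Usage within loci followed the same division. By Fisher's exact test at the same depth with Benjamini-Hochberg adjustment, the distal share differed at 13 of 5070 loci between libraries 1 and 2 and at 5 between libraries 3 and 4. It differed at 565 between libraries 1 and 3, 471 between libraries 1 and 4, 832 between libraries 2 and 3 and 725 between libraries 2 and 4. The SD over 4 libraries given with each value therefore includes this difference, and neither the labels nor the table give a batch that would allow a value within batches.

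Narrow regions differed most. The 2489 regions of 5 bases or fewer had mean levels of 7.24 and 6.41 CPM in libraries 1 and 2 and 0.682 and 0.723 in libraries 3 and 4. Library 1 was 10.6-fold above library 3, and library 2 was 8.86-fold above library 4. These regions took 1.80% (1.79% to 1.81%) and 1.59% (1.58% to 1.61%) of the reads in libraries 1 and 2 and 0.170% (0.166% to 0.173%) and 0.180% (0.176% to 0.184%) in libraries 3 and 4. No reads were counted at 1426 and 1480 of them in libraries 3 and 4, against 0 and 26 in libraries 1 and 2. Every region had at least 11 reads in its highest library, so a region highest in library 1 could not be at 0 there. This can also raise the ratio of library 1 to library 3. An example is the single base 54026527 on the minus strand of chromosome 12, with 691, 314, 15 and 14 reads in libraries 1 to 4. Other narrow regions did not follow: the single base 34833959 on the minus strand of chromosome X had 248, 71, 470 and 352 reads. Regions of 41 bases or more had means of 82.8, 83.5, 87.9 and 87.7 CPM. Narrow regions mostly stood alone: 95.0% of those of 5 bases or fewer had no neighbour on their strand within 5 kb, against 31.2% of regions wider than 10 bases. A passing region of 10 bases or fewer was present at 274 of the 5070 loci compared above.

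**Figure D3:**
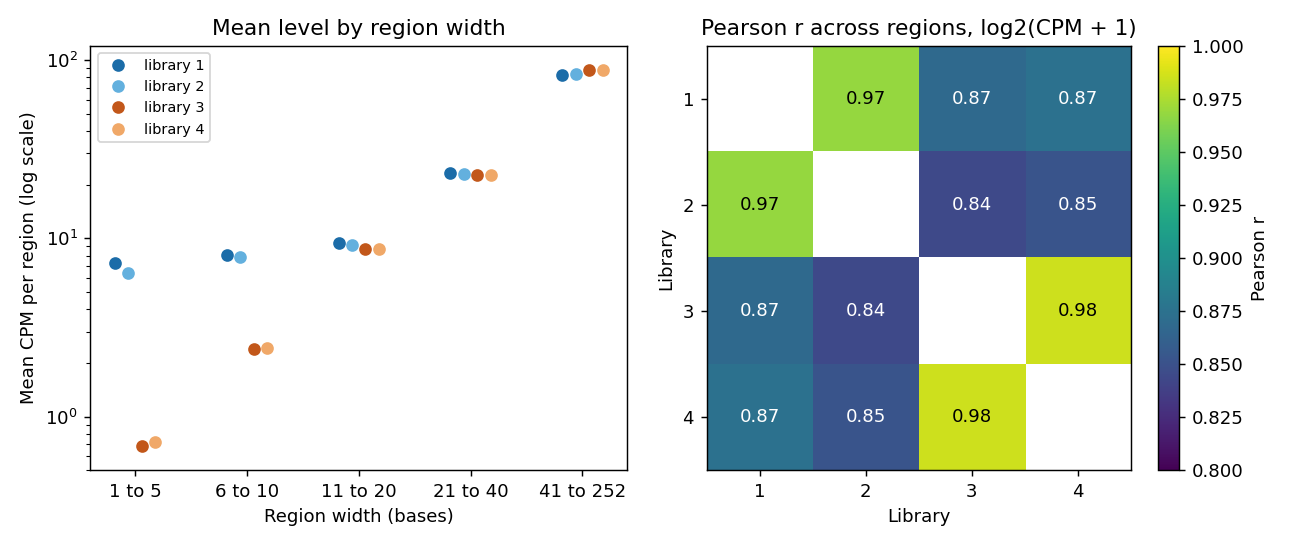
Left: mean CPM per region (y axis, log scale) by region width (bases, x axis) in the 4 libraries; regions of 1 to 5 bases lie at 7.24 and 6.41 in libraries 1 and 2 and at 0.682 and 0.723 in libraries 3 and 4. Right: Pearson's r across regions for each pair of libraries, with 0.97 and 0.98 for libraries 1 and 2 and libraries 3 and 4.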

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

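Of 69 values tested for a library far from the other 3, 1 stood apart. Chance flags about 1 in 20, so this is no more than chance gives. The distal share of the locus on the minus strand of chromosome 7 (44605008 to 44605434) was 4.63% in library 3, against 5.26%, 5.24% and 5.17% in libraries 1, 2 and 4. The distal region held 47, 21, 50 and 40 reads in libraries 1 to 4, so counting noise could give such a gap. No explanation was tested.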

How the results depend on the processing

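The strongest region was the most 3' one more often than random placement gives under all 15 alternatives run, from 47.5% to 51.3% of loci. Each had a p of 0.0002 from draws of random placement, the smallest the draws can give. The alternatives use the same libraries and are not independent tests. The value at random changed with the setting. The excess was smallest with a 10% minimum (50.8% against 44.3% at random) and in libraries 3 and 4 alone (47.9% against 41.4%), and largest with no minimum (47.5% against 37.9%) and in libraries 1 and 2 alone (50.1% against 40.6%). The joining distances of 1, 2 and 10 kb, the removal of regions of 10 bases or fewer and the fits on libraries 1 and 2 or 3 and 4 alone were chosen after seeing the data. Leaving out a library gave 29.7% to 31.7% of loci with several regions, a median distal share of 41.8% to 42.7% and 43.7% to 44.8% of loci above 50%. The share of loci with several regions was 34.9% with no minimum, 25.4% with a 10% minimum, 27.6% with ends within 100 bases merged, 19.5%, 23.9% and 34.1% with joining within 1, 2 and 10 kb, 35.1% without regions of 10 bases or fewer and 30.2% and 34.1% in libraries 1 and 2 and 3 and 4 alone. With only loci of 500 reads or more, 6016 loci remained by construction, of which 2999 (49.9%) had several regions. The median distal share was 39.4% with no minimum, 44.3% with 50 reads, 45.6% with a 10% minimum and with merged ends, 40.7% in loci of 500 reads or more, 47.6%, 45.1% and 42.0% with joining within 1, 2 and 10 kb, and 43.2% and 41.2% in libraries 1 and 2 and 3 and 4 alone. The share of loci above 50% was 43.3%, 44.8%, 45.5% and 46.4% with no minimum, 50 reads, a 10% minimum and merged ends, 47.8%, 45.8% and 43.8% with joining within 1, 2 and 10 kb, and 45.4% and 43.8% in libraries 1 and 2 and 3 and 4 alone. With a pseudocount of 0.1, r fell to 0.76 (libraries 1 and 3), 0.77 (1 and 4), 0.73 (2 and 3) and 0.74 (2 and 4); the cause was not tested. Without regions of 10 bases or fewer, r of these pairs rose to 0.921, 0.927, 0.887 and 0.895, and with only regions of 50 reads or more it was 0.861, 0.868, 0.831 and 0.839. Of 375 values sought for the 25 named loci with several regions, 292 moved by less than the SD between libraries, 35 by more and 48, at 17 loci, could not be had. In 14 of these 48 the locus was split, and in the others too few regions or reads were left. Of the 25 loci, 16 moved by more than the SD under at least 1 alternative. All 25 held over 500 reads, so the minimum of 500 reads could not change their values. Depth limits library 2 most, where a count of 0 allows 1.39 CPM. Settings that need gene names, an annotation or a genome sequence were not run. No paired analysis was possible because the series has 1 group.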

Other observations

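Overlapping poly(A) regions on opposite strands were more common than chance placement gives. There were 171 overlapping pairs, against a median of 10 and at most 21 in 100 random shifts of the minus strand along each chromosome. The pair best read on both strands lay on chromosome 16, with 13296 reads on the plus strand (2011952 to 2011988) and 8952 on the minus strand (2011908 to 2012061). The next were on chromosome 20 (2639009 to 2639054, 8081 reads, and 2639030 to 2639071, 3732 reads) and on chromosome 19 (5691838 to 5691906, 3692 reads, and 5691829 to 5691883, 3574 reads). A technical source would be reads of a transcript counted on both strands, which predicts counts that rank together. They did not: across the 171 pairs Spearman's rho was -0.0294 (bootstrap interval -0.19 to 0.13; permutation p = 0.70), and the stronger strand had a median of 4.09 times the reads of the weaker. Transcripts that converge and end within each other remain a candidate explanation, untested without an annotation.

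In the next paragraphs, the tests of depth for narrow regions, of narrow regions as the whole division and of batch labels were chosen after the result was seen.

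The narrow regions of libraries 1 and 2 are the pattern to follow up first. Lower depth in libraries 3 and 4 is argued against by the totals: they held 5713530 and 3984278 reads against 2163977 in library 2, 1.84 times as many or more, yet had no read at 57.3% and 59.5% of these regions, against 1.04% in library 2. An even spread over the genome stays open. With chromosome Y left out, neither the absence of a correlation nor the positive one set beforehand as evidence against it was met. Across 23 chromosomes (all but Y) narrow regions per Mb were fewer where wider regions were denser (Spearman rho = -0.48, permutation p = 0.021; Pearson r = -0.53, p = 0.019; both 0.021 after adjustment over the pair; r = -0.43 without chromosomes 19 and 17). Chromosome Y, with 15 regions, was lowest in both measures (0.384 narrow and 0.0699 wider regions per Mb). Including it would weaken the negative relation, and no correlation with it was run. Leaving Y out was not set beforehand, and whether either outcome is met with Y included was not computed. Chromosome length was taken as the last region's end and includes unassembled stretches. Material with no strand relation to nearby transcripts stays open. For 573 isolated narrow regions the next wider region downstream was on the same strand in 55.8% (51.8% to 59.9%). The interval lay above 50%, but not wholly above 55%, the bound set beforehand. Oligo(dT) priming on A-rich stretches of DNA or RNA may account for isolated piles of a few bases, and was not tested without a sequence; no biological explanation was tested.

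The division of the libraries into 1 and 2 and 3 and 4 is wider than the narrow regions. If libraries varied independently, the 2 highest libraries of a region would be 1 and 2 or 3 and 4 in 33.3% of regions. They were in 65.6% of all regions, and in 62.0% of those wider than 10 bases, so narrow regions are not the whole of it. They carry part of it: without regions of 10 bases or fewer, Pearson's r between libraries of different pairs rose from a range of 0.84 to 0.87 to one of 0.887 to 0.927, still below the 0.971 of libraries 1 and 2 and the 0.983 of libraries 3 and 4. Counting noise is argued against, since the share was 78.2% among the 3453 regions of 1000 reads or more. A shared day or batch of culture or library preparation may underlie it, and stays open because 0 labels give a batch or day. A difference between cultures of the line cannot be told apart from a difference in preparation for the same reason.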
